A study of Mus musculus with 48 samples.

How the data were processed

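RNA of murine erythroleukemia cells was compared on 2-colour cDNA arrays. Each of the 48 arrays carried RNA of a clone that differentiates readily on induction (HD) and of a clone that does so poorly (LD), both treated with the same drug for the same time. There were 12 conditions, from 3 drugs and 4 times, with 4 technical arrays each, per the labels. No untreated cells were analysed here, and each kind of cell was represented by a single clone. Tests across conditions therefore measure the spread between conditions that is left after drug and time are accounted for. They do not measure the spread between clones or cultures.

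Each array had been deposited as 2 parts, giving for every listed cDNA clone an intensity in a column for the control RNA and an intensity in a column for the target RNA, per the file headers. The deposited intensity values carried no background column, no flag and no block, and none was at or below 0. They were taken as already corrected for background, and no further correction was made. How the authors chose which clones to list is not given in the sources used here. The files listed 22171 clones in all, 11374 in part 1 and 10797 in part 2, and between 19237 and 20581 on one array. A further table of the authors held log2 ratios of the same arrays in 22656 rows, 496 of them empty. Set against the ratios computed here, its columns had r between 0.987 and 0.999 across clones and slopes between 0.965 and 0.998, so that its scale was log2 and its direction target over control. Column medians of the authors' log2 table lay between -0.040 and 0.021. Its normalization method is not given in the sources used here. It was used as an alternative only.

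The labels name HD cells as target and LD cells as control on all 48 arrays. They also give HD cells the dye Cy3 on every array, while the channel order is turned on arrays 3 and 4 and the design text speaks of dye swaps. A rule written before the data were examined said that arrays 3 and 4 would be turned if their raw ratios correlated negatively with those of arrays 1 and 2. They did, with mean correlations between -0.82 and -0.38 across clones. After the loess normalization described below, these lay between -0.52 and 0.02. That rule presumed columns by dye, whereas the files have columns by sample. Target over control was therefore kept as HD over LD on every array, against the letter of the rule. This decision was made after the outcome of both choices had been seen. The direction HD over LD is called likely on this basis, and the counts of each comparison with arrays 3 and 4 turned are given beside the main ones. Counts of single conditions, and of fits that leave out arrays or conditions, are given in the main direction only, except those under TSA at 36 h.

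Within each part of each array, log2(HD/LD) was normalized by loess on mean log2 intensity with a span of 0.3. The value of a condition was the mean of 2 means, that of arrays 1 and 2 and that of arrays 3 and 4. A dye bias specific to a clone cancels in it if it is of equal size on both pairs. Across clones, the difference between the 2 means, divided by 2, had a median SD of 0.30 over conditions, against 0.21 for the condition values. The planned filter on signal over background could not be applied without background values. Tested clones had a value in both pairs of arrays in all 12 conditions, which left 18494. The 12 values were fitted in limma 3.58.1 under R 4.3.3 with drug and time as additive terms, 6 residual degrees of freedom and empirical Bayes moderation. Adjusted p-values are Benjamini-Hochberg over all tested clones, two-sided, with a threshold of 0.05. Changes within each line were fitted on single-channel log2 intensities after between-array quantile normalization of mean intensities, with condition as a random block. A separate count of clones at least 2-fold different in a condition, with the same sign on all 4 arrays, carries no test.

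Same-numbered arrays of different conditions deviated together from their condition means, with r between 0.21 and 0.68 across clones. The difference of array 1 from array 2 did not, with a median r of 0.01, and that of array 3 from array 4 had a median r of 0.00330. The numbers therefore pair arrays by orientation. A fit of all 48 arrays with the replicate number as a block is given beside results that it moved by over 1.5 times. That fit takes technical arrays as units, with a correlation of 0.077 within a condition. Its larger counts therefore do not come from more independent samples.

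The statistics were tested on simulated arrays of the 18494 clones, with 200 clones changed. Each clone was given 1 dye bias, the same in all conditions, which cancels in the mean, and noise independent between clones. In the data the difference between the array pairs had r between 0.39 and 0.79 between conditions. A bias that varies between conditions was not simulated, so the shares below hold for the simulated setting. For the ratio over all conditions, 98% of clones changed by 0.5 on the log2 scale were called. For the difference of TSA from DMSO, 3% of clones changed by 0.5 and 88.5% of those changed by 1 were called. For 36 h minus 6 h, 0% of clones changed by 0.5 and 89% of those changed by 1 were called. Of the calls made there, up to 8.26% were of unchanged clones. For the change within HD cells, 34% of clones changed by 1 were called. There, condition values and not arrays were simulated, with a shared spread that was set and not estimated from the data.

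The rule for naming features asked for gene symbols. Of the clone names, 0 were found in the reference gene table, and the files do not pair them with genes. The planned gene lists were therefore not run, and the text names the largest called change each way for the ratio over all conditions and for 36 h minus 6 h, as clone names. Alternatives covered normalization, filter, model, orientation, single arrays, single conditions, array weights and the authors' table. Those chosen after the data were seen are named as such in the closing section.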

Results

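The data compared transcript levels between 2 clones of the murine erythroleukemia line T-3-Cl-2-0.fl, a line of red cell precursors arrested by transformation that can be induced to mature in culture. HD cells are a clone of high inducibility and LD cells a clone of low inducibility. Both were treated with 1.0% dimethyl sulfoxide (DMSO), 3.0 mM hexamethylene bisacetamide (HMBA) or 15 nM trichostatin A (TSA), an inhibitor of histone deacetylases, for 6, 12, 24 or 36 h. Each of the 12 conditions was measured on 4 technical arrays, and a median of 20031 clones was listed per array. The number of arrays limits the precision of each value. Within a condition, the mean of arrays 1 and 3 had r between -0.03 and 0.71 with that of arrays 2 and 4 across clones. The median was 0.40, with -0.03 under HMBA at 12 h and -0.008 under TSA at 6 h. Ratios of different conditions had r between -0.22 and 0.62, with a median of 0.18.

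Across all conditions, clone H4004H01 was the clone with the largest called excess in HD cells. Its log2(HD/LD) was 1.19 with a 95% confidence interval from 1.09 to 1.30 (12 conditions, adjusted p = 2.68e-09 in limma), and it was above 0 on 47 of 48 arrays. The interval uses the spread left after drug and time, whereas the 12 values themselves had an SD of 0.51. Clone H4016F12 had the largest called deficit, with a log2 ratio of -1.92 and an interval from -2.14 to -1.71 (adjusted p = 1.75e-08), below 0 on all 48 arrays. Of 18494 clones tested, 816 were higher and 331 lower in HD cells. The median absolute log2 ratio of the called clones was 0.23, and 4 of the higher and 11 of the lower clones differed at least 2-fold. The ratio had the same sign in all 12 conditions for 311 of the higher and 105 of the lower clones. With arrays 3 and 4 turned, 10372 clones were called, with 4911 higher and 5461 lower, so that lower clones were then in excess. Of these, 1549 higher and 2056 lower clones had the same sign in all 12 conditions, and 0 higher and 58 lower differed at least 2-fold. The value of H4004H01 then became 0.16 (adjusted p = 0.0159) and that of H4016F12 0.18. The fit of single arrays with the replicate number as a block, which takes technical arrays as units, called 1730 clones. Median centring in place of loess called 653.

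**Figure D1:**
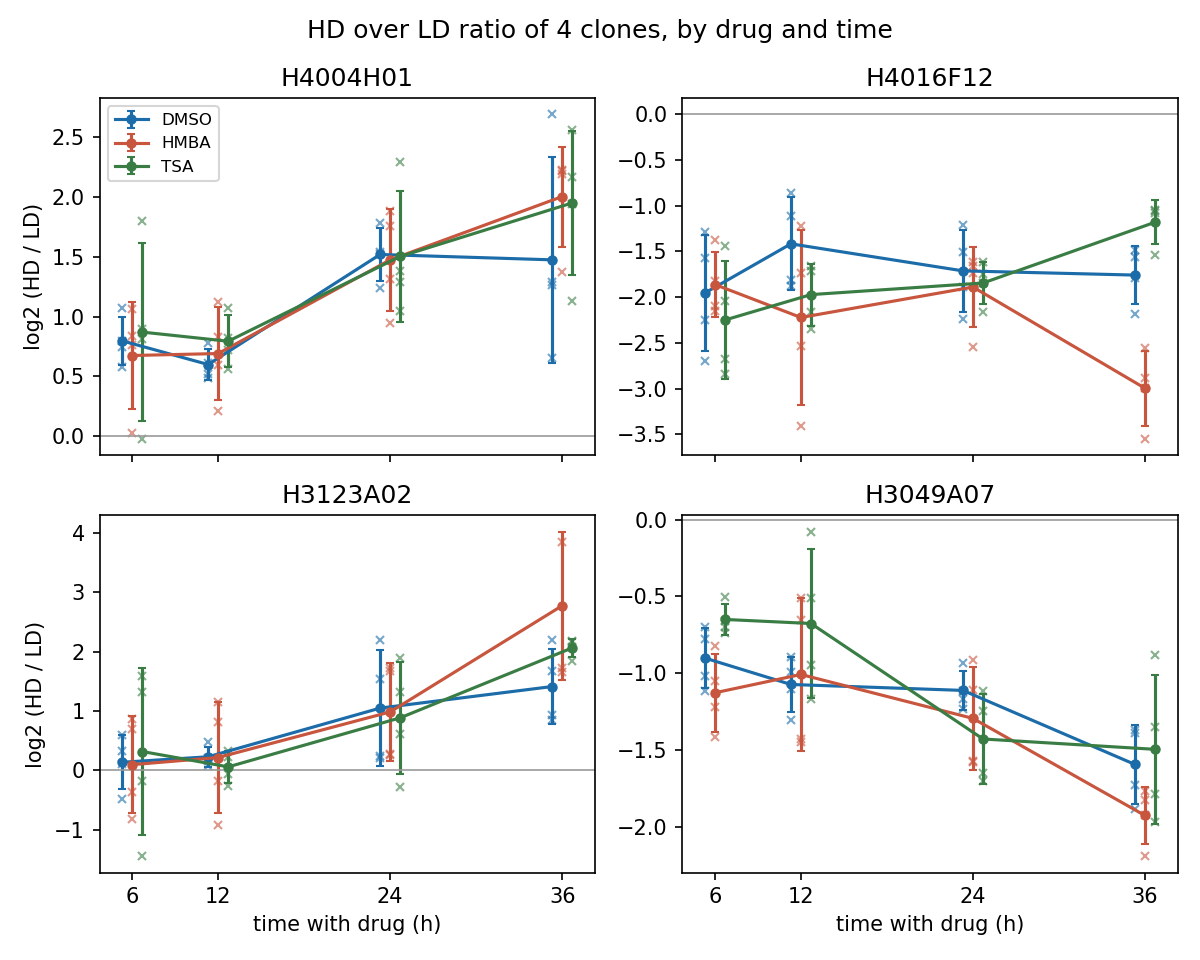
Log2 ratio of HD over LD cells (y axis) against hours with the drug (x axis) for 4 clones; dots are condition means, bars 1 SD of the technical arrays, crosses single arrays, and colours the drugs. H4004H01 was above 0 on 47 of 48 arrays, and H4016F12 and H3049A07 were below 0 on all 48. H3123A02 was above 0 on 37 and below 0 on 10 of its 47 arrays.

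The ratio under each drug was taken as the mean of its 4 times. Under DMSO, H4004H01 had a log2 ratio of 1.10 ± 0.47 (SD, n = 4 times), under HMBA 1.21 ± 0.65 and under TSA 1.28 ± 0.55. H4016F12 had -1.71 ± 0.22 under DMSO, -2.24 ± 0.53 under HMBA and -1.81 ± 0.45 under TSA. Under DMSO 27 clones were higher and 32 lower in HD cells, under HMBA 228 and 95, and under TSA 266 and 176. Among these, 17 clones were higher and 29 lower under all 3 drugs, and 0 were higher under one drug and lower under another. HMBA and TSA shared 84 higher clones, where independent lists would share 3.28, and 50 lower clones, where 0.904 would be shared. Turning arrays 3 and 4 gave 680 clones higher and 1331 lower under all 3 drugs, and 45 were higher under one drug and lower under another. HMBA and TSA then shared 1288 higher and 1939 lower clones, where 312.3 and 474.5 would be shared by independent lists. The 3 lists come from separate arrays but from the same pair of clones and the same estimate of spread.

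These counts rested on few conditions. Without DMSO at 6, 12 or 24 h the DMSO count of 59 fell to 25, 31 and 30, with 6, 10 and 7 higher against 19, 21 and 23 lower, and without TSA at 36 h it was 140. The HMBA count of 323 became 75, 69, 87 and 66 without HMBA at 6, 12, 24 and 36 h, and then 35, 31, 39 and 29 clones were higher against 40, 38, 48 and 37 lower. It was 205 without DMSO at 6 h, 149 without array 1 of every condition and 210 without array 3. The TSA count of 442 became 106, 80 and 71 without TSA at 12, 24 and 36 h, with 46, 44 and 22 higher against 60, 36 and 49 lower. It was 24 in a model of the 4 TSA conditions alone, without a time term, with 4 higher and 20 lower. Leaving out DMSO at 6 h gave 286, and leaving out array 4 of every condition 257. Without array 1 of every condition it was 192, with 94 higher and 98 lower. Median centring gave 8 higher and 18 lower clones under DMSO, 32 and 37 under HMBA and 81 and 34 under TSA. With the replicate number as a block the counts were 428, 736 and 1274, with 324, 541 and 783 higher against 104, 195 and 491 lower. Under DMSO higher clones were then in excess, but that fit takes technical arrays as units. Which side was in excess varied between fits under each of the drugs. With arrays 3 and 4 turned the counts were 4786, 5493 and 5242. Of these, 1948, 2434 and 2373 were higher against 2838, 3059 and 2869 lower, an excess of lower clones under each drug.

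No clone differed between drugs in the main limma fit. For H4004H01 the ratio under HMBA minus that under DMSO was 0.11 on the log2 scale, with a 95% confidence interval from -0.13 to 0.36, and TSA minus DMSO was 0.18, from -0.07 to 0.43. For H4016F12 HMBA minus DMSO was -0.53, from -1.06 to -0.0072, with an adjusted p of 0.995. HMBA against DMSO gave 0 calls and 748 clones at an unadjusted p under 0.05, where chance gives 924.7. TSA against DMSO gave 0 calls and 2188 such clones, and TSA against HMBA 0 calls and 1510. The median half-width of the 95% interval of a difference, unadjusted for the number of clones, was 0.26 on the log2 scale. The 0 calls do not exclude differences above that size. For TSA minus DMSO, 3% of simulated differences of 0.5 were called, and uncalled estimates ran from -0.89 to 1.00. The blocked fit called 0, 2 and 1 clones in these comparisons, and turning arrays 3 and 4 gave 21, 120 and 0.

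Between 6 and 36 h the ratio moved towards HD cells for 27 clones and towards LD cells for 1. The largest rise was that of H3123A02, whose log2 ratio was higher at 36 h than at 6 h by 1.90, with an interval from 1.43 to 2.36 (adjusted p = 0.00126 in limma). Its ratio at 36 h was 1.41 under DMSO, 2.77 under HMBA and 2.06 under TSA, against 0.14, 0.10 and 0.32 at 6 h. Array 1 of HMBA at 36 h had no value for it. The 2.77 thus weighs array 2, with 3.85, as much as arrays 3 and 4 together, with 1.66 and 1.73. Without HMBA at 36 h its rise was 1.55 (adjusted p = 0.005 in limma). Under TSA at 6 h arrays 1 and 2 had 1.59 and 1.32, and arrays 3 and 4 -0.18 and -1.44. H3123A02 was above 0 on 37 and below 0 on 10 of its 47 arrays. H4004H01 was also among the rising clones, by 1.03 (adjusted p = 0.00248). H3049A07 fell by 0.78 (adjusted p = 0.0493), and it lost its call in 22 of 32 alternatives; with arrays 3 and 4 turned its value was -0.12 (adjusted p = 0.998) and that of H3123A02 -0.16. All 27 rising clones rose under each of the 3 drugs. With arrays 3 and 4 turned 4 did, and the median change of the 27 fell from 1.43 to -0.01. The 27 were chosen for a high mean of these same 3 differences in the main direction, so both results follow largely from the choice. The median log2 ratio of the 27 at 36 h was 0.90 under DMSO, 1.78 under HMBA and 1.94 under TSA, and at 6 h it was 0.01, 0.28 and 0.09. Median centring gave 0 calls and arrays 3 and 4 turned gave 0. A model of the conditions at 6 and 36 h alone, without a drug term, gave 0, while the blocked fit gave 127. The count was 17 without DMSO at 12 h, 78 without DMSO at 36 h, 17 without HMBA at 6 h, 14 without HMBA at 36 h, 14 without TSA at 6 h and 17 without array 3 of every condition.

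Single-channel intensities were compared between 6 and 36 h within each line. The 27 rising clones were chosen for a rise of HD over LD on the same arrays, so a larger change in HD than in LD cells follows from the choice. Within HD cells 25 of the 27 rising clones were called higher at 36 h than at 6 h, with a median change of 1.79 on the log2 scale. Within LD cells 4 of the 27 were called higher, with a median change of 0.70, and 24 had an estimate above 0. With loess within arrays alone 3 and 0 of the 27 were called higher in HD and LD cells, and without DMSO 17 and 0. Without TSA it was 15 and 1, and without array 2 of every condition 18 and 2 of 25 clones. With arrays 3 and 4 turned 21 and 20 were, with medians of 1.32 and 1.19. H3123A02 rose by 2.91 ± 0.36 (SE) in HD cells (adjusted p = 0.000157 in limma), and its estimate in LD cells was 1.01 ± 0.36 (adjusted p = 0.107). H3049A07 rose by 0.98 ± 0.25 in LD cells (adjusted p = 0.0372), with an estimate of 0.20 ± 0.25 in HD cells (adjusted p = 0.662). The LD call of H3049A07 was lost in 7 of 12 alternatives, among them loess alone (adjusted p = 0.359) and the fits without DMSO (0.448), HMBA (0.156) or TSA (0.0954). H3123A02 in HD cells lost its call with loess alone (adjusted p = 0.0522), and in LD cells it was called without HMBA, with 1.49, with the offset, with 0.97, and with arrays 3 and 4 turned, with 2.04.

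**Figure D2:**
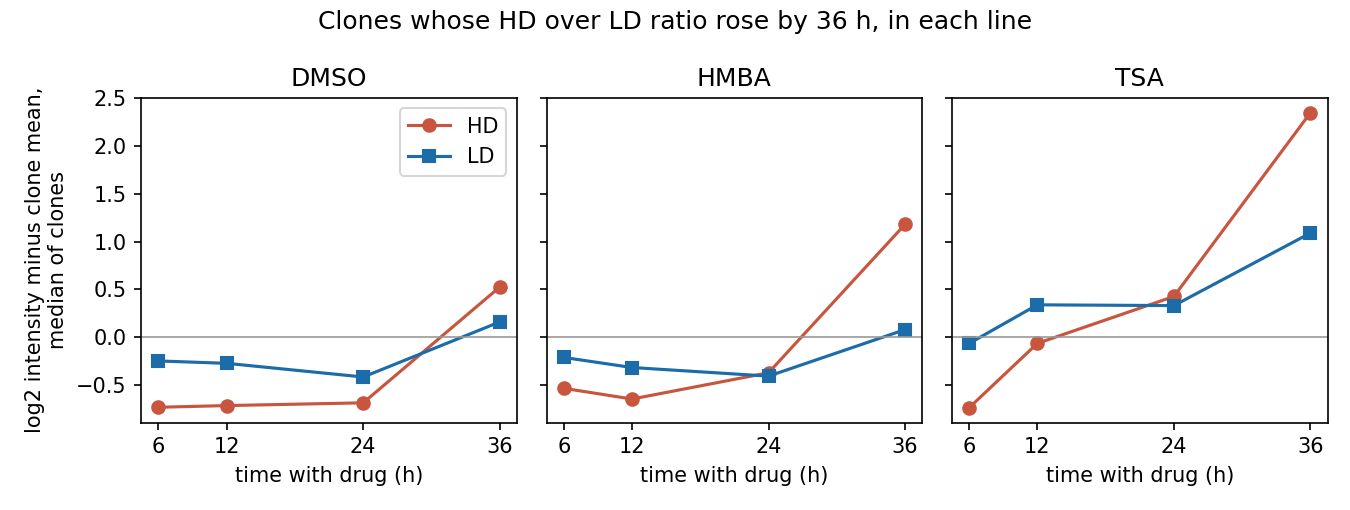
Median over the 27 rising clones of log2 intensity minus each clone's mean over the 12 conditions (y axis) against hours with the drug (x axis), for HD and LD cells in 1 panel per drug. Under TSA the median went from -0.74 at 6 h to 2.35 at 36 h in HD cells and from -0.07 to 1.09 in LD cells.

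Over all clones, 721 rose and 594 fell from 6 to 36 h within HD cells, and 377 rose and 313 fell within LD cells. Both lines shared 324 rising clones, where independent lists would share 14.7, and 266 falling clones, where 10.1 would be shared. The lines were read from the same arrays, so part of this excess may come from the arrays. These counts depended on the scaling between arrays: with loess within arrays alone, 3 clones were called in HD cells and 0 in LD cells. Without DMSO the counts were 20 and 0, without TSA 106 and 289, without array 2 of every condition 112 and 18, and without array 4 728 and 345. Without array 1 the LD count was 1096. With arrays 3 and 4 turned 870 rose and 689 fell within HD cells, and 414 rose and 270 fell within LD cells; both lines then shared 396 rising and 237 falling clones, where 19.5 and 10.1 would be shared.

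In single conditions, the number of clones at least 2-fold different with the same sign on all 4 arrays was highest under TSA at 36 h, with 130 higher and 25 lower in HD cells. The next highest number of higher clones was 24, under HMBA at 36 h, where 28 were lower. Under DMSO at 36 h 12 were higher and 21 lower. At 6 h 1 clone was higher under DMSO, 2 under HMBA and 0 under TSA, against 4, 20 and 13 lower. Each condition was 1 pair of RNA extracts, so these counts have no replicate check. Over all conditions they summed to 197 higher and 170 lower. Without array 3 of every condition the sum of 367 became 563, and 223 clones were higher under TSA at 36 h. With arrays 3 and 4 turned the sum was 2044, with 330 higher and 1714 lower, and the number higher under TSA at 36 h was 11, below the 104 of the highest other condition.

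**Figure D3:**
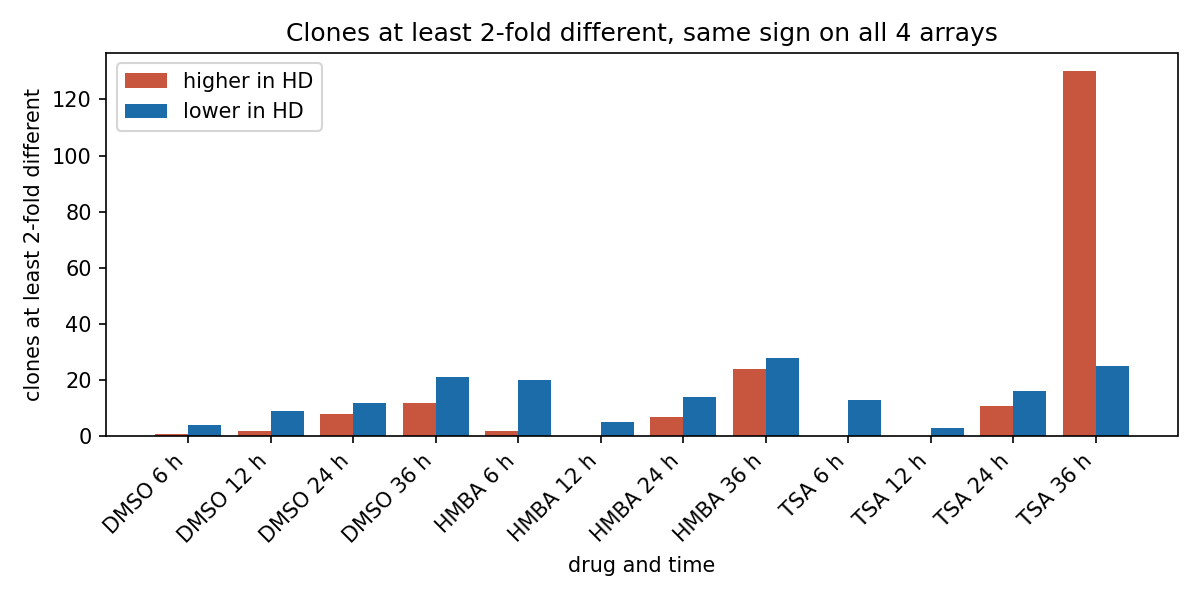
Number of clones at least 2-fold different between HD and LD cells with the same sign on all 4 arrays (y axis) in each drug and time (x axis), higher and lower in HD cells as separate bars. TSA at 36 h had 130 higher clones and HMBA at 36 h had 24.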

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

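Tests of the intensity floor, of whole plates, of consecutive wells, of array part 2 and of TSA at 24 h were chosen after the results they bear on had been seen. The other tests of this part were set down before their own results, but after the counts under both directions of arrays 3 and 4, and the values of the TSA clones on single arrays, had been seen.

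The change from 6 to 36 h differed between HD and LD cells for 28 clones by the test of that difference. Of 10 splits of the 6 conditions at 6 and 36 h, the real one gave 28 and the highest other 0, which is too few splits for a share under 0.05. Among single arrays, 3 values stood apart from the other 3 of their condition. H4004H01 had 1.38 on array 3 of HMBA at 36 h, where the others lay between 2.19 and 2.22. H4016F12 had -2.54 on array 4 of HMBA at 24 h, against -1.74 to -1.62, and -1.54 on array 3 of TSA at 36 h, against -1.08 to -1.04. Chance flags about 1 in 20 groups, which is 3.55 of the 71 tested.

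Arrays 1 and 2 of a condition correlated negatively with arrays 3 and 4 in raw ratios, and both tests below argue against turning arrays 3 and 4, which the rule written beforehand would have done. If the columns held dyes, the brighter floor would stay in its column, but on 48 of 48 arrays the higher 1st percentile of intensity lay in the HD column on arrays 1 and 2 and in the LD column on arrays 3 and 4. A constant dye bias cancels in the change from 6 to 36 h, and of the 50 clones with the largest change on arrays 1 and 2, 41 had the same sign on arrays 3 and 4. In the other direction 37 of 50 did, as a clone-specific dye bias with columns by sample may give. The sets of 50 shared 24 clones, so these counts are not independent of each other. Over all clones the changes of the array pairs had an r of only 0.0080, so the argument from the change with time rests on the clones that moved most.

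The 27 clones that rose towards HD cells carried 18 plate numbers, with at most 5 on 1 plate, but 6 pairs of them sat in consecutive wells by their names, against at most 2 in 10000 random sets. A shift of whole plates is argued against by the 1561 other clones with the same plate numbers, whose median change was 0.0070 on the log2 scale. A patch on the slide stays open: the 134 uncalled clones listed within 3 lines had a median of 0.0041, but the files do not give slide positions. After removal of drug and time, residuals of the rising clones had a mean pairwise r of 0.53, and sets of other clones higher in HD cells reached at most 0.34. Those sets were not chosen for a change with time, as the 27 were. A rise of unequal size between drugs also stays in these residuals, so part of the higher r may follow from the choice. Several clones of one transcript, or carry-over between wells, could give such an r, as could separate genes regulated together. No sequence was at hand to part them.

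TSA at 36 h had 130 clones at least 2-fold higher in HD cells, and a fault of part 2 is argued against as the whole cause, since part 1 alone had 35 and at most 7 in another condition. A dye bias of equal size on both pairs of arrays cancels in this mean, and how far one of unequal size could add to it stays open. The pairs were counted by their mean alone among the tested clones, without the rule on sign. Arrays 1 and 2 then gave 716 clones at least 2-fold higher, against at most 408 in another condition. Arrays 3 and 4 gave 190, against at most 556 in another condition. Of the 716, 491 were above 0 on arrays 3 and 4, and the median of all 716 there was 0.21, between the bounds set beforehand and above the 0.15 of the highest other condition. Those of the 130 clones that were tested in all conditions had a median of 0.06 under TSA at 12 h and 0.61 at 24 h, as a response building up with time may give, but it was also 0.37 under HMBA at 24 h, and under TSA at 24 h it was 0.94 on arrays 1 and 2 and 0.21 on arrays 3 and 4. One pair of extracts was made for this condition, and a fault of that pair was not tested.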

How the results depend on the processing

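An added offset of 50 in both channels, the filter of at least 24 arrays with missing conditions, the removal of the dimmest 25% of clones and the regression on dye bias were chosen after seeing the data. Turning arrays 3 and 4 was what the rule written beforehand asked for. It became an alternative only when the main direction was chosen, after both outcomes had been seen. The other alternatives were set before the data were examined. Not run were other background corrections and print-tip loess, since the files give neither background nor blocks, and the gene lists, since no clone has a gene name. Dim clones limit what can be called, as no signal over background was at hand. Of the 31 alternatives to the 1147 clones different over all conditions, 25 stayed within 1.5 times. The authors' table gave 1183, of which 1115 were the same clones. Where a count moved, the cause was not tested, unless fewer arrays or conditions entered. Counts below follow the order all conditions, DMSO, HMBA, TSA and 36 h minus 6 h.

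Median centring gave 653, 26, 69, 115 and 0. The fit of single arrays with the replicate number as a block gave 1730, 428, 736, 1274 and 127, and that without a replicate term 1929, 466, 926, 1543 and 143. Both fits take technical arrays as units. Arrays 1 and 2 alone gave 7585, 2469, 2443, 2130 and 9, and arrays 3 and 4 alone 8664, 2268, 3758, 5181 and 7; a dye bias does not cancel in these. Arrays 3 and 4 turned gave 10372, 4786, 5493, 5242 and 0. The model without the other term, fitted to the conditions of each comparison alone, gave 139 for HMBA, 24 for TSA and 0 for 36 h minus 6 h. Clones on all 48 arrays gave 98 for DMSO and 49 for 36 h minus 6 h, where the authors' table gave 43. The offset gave 184 for DMSO, 1035 for TSA and 75 for 36 h minus 6 h, and leaving out the dimmest 25% of clones 137, 669 and 66. Leaving out an array number or a condition gave 780 to 1244 for all conditions, 25 to 140 for DMSO, 66 to 462 for HMBA, 71 to 549 for TSA and 14 to 78 for 36 h minus 6 h.

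The differences between drugs, 0 in the main limma fit with 748, 2188 and 1510 clones at an unadjusted p under 0.05, stayed at 0 in each leave-one-out fit, from 0 to 0. In the order HMBA minus DMSO, TSA minus DMSO and TSA minus HMBA, the fit with the replicate block gave 0, 2 and 1, that without a replicate term 1, 17 and 6, and arrays 3 and 4 turned 21, 120 and 0. Arrays 3 and 4 alone gave 275 for TSA minus DMSO.

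Within HD and LD cells, loess alone gave 3 and 0, and the offset gave 1172 in LD cells. Leaving out a drug or an array number gave 20 to 1859 in HD cells and 0 to 1096 in LD cells. The count of clones at least 2-fold different, summed over conditions so that a clone can count more than once, was 367. It became 2641 at 1.5-fold, 84 at 3-fold, 561 with median centring and 2044 with arrays 3 and 4 turned. Without 1 array number it was 393 to 563. With arrays 3 and 4 turned H4016F12 had 0.18 over all conditions and H3123A02 -0.16 for 36 h minus 6 h, both reversed; H4004H01 had 0.16 and H3049A07 -0.12. H3049A07 within HD cells had -0.13 with loess alone. H3123A02 lost its call, with the same direction, in 3 further alternatives.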

Other observations

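All regroupings of this part were set down before their results were seen. Sign flips of the 12 conditions tested whether ratios that kept their sign across conditions could be chance. Of 100 patterns 1, the real one, gave as many as 1147 called clones, and the highest other gave 108. Chance signs of the conditions are excluded at that share. Anything that all conditions share passes the flips, so they cannot test it. Examples are the single pair of cell clones and a dye bias of unequal size on the array pairs. For single drugs 8 patterns exist, too few for a share under 0.05. There the real counts were 59 under DMSO, 323 under HMBA and 442 under TSA, 1 pattern reached each, and the highest others were 0, 1 and 21.

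Between drugs, 35 splits of 8 conditions were counted by clones at an unadjusted p under 0.05. For HMBA against DMSO 15 splits gave as many as the real 748, and the highest other gave 2905. For TSA against DMSO 5 splits gave as many as 2188, with 3279 as the highest other, and for TSA against HMBA 6 gave as many as 1510, with 2513 as the highest. The split with 2513 set 6 and 24 h against 12 and 36 h under both drugs. Chance is not excluded for these counts, and the splits cannot decide it. The real split balances the times between its sides, whereas the others need not. The time term was kept in each split, so a change with time common to the drugs is removed. One that differs between drugs can still be counted in the other splits. The split with 2905 set DMSO at 6, 24 and 36 h and HMBA at 36 h against the other conditions; what these share was not tested. For the change with time within a line there were 10 splits, too few for a share under 0.05; 1 gave as many as the real 1315 in HD cells and 690 in LD cells, with 27 and 3 as the highest others.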
